A study of Mus musculus with 8 samples.

How the data were processed

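Gene expression was measured by RNA sequencing in cardiac fibroblasts of the mouse, isolated by fluorescence-activated sorting for PDGFRα, a growth factor receptor that marks fibroblasts. The hearts were taken 7 days after a coronary artery had been occluded, so the cells came from a healing infarct. Per the labels' protocols, both groups of mice had received tamoxifen, RNA was extracted with Trizol, and poly(A) RNA libraries were made with a NEBNext Ultra kit without any culture step. The 8 samples fell into 2 groups of 4 by their genotype label. FTbR2KO denotes fibroblast-specific loss of the TGF-β type 2 receptor TbR2, encoded by Tgfbr2, and TbR2fl/fl denotes the controls that carry the floxed gene. Nothing in the labels says outright that each sample came from a separate animal, so p-values measure the spread between these samples. The titles number the samples 1 to 4 and 5 to 8, and these numbers are kept here.

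The values were the authors' gene-level FPKM (fragments per kilobase of gene length, scaled to sequencing depth), used as deposited for 54532 genes with the names, coordinates, lengths and biotypes per the file headers. The submitters' processing notes name CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1 and the builds mm10 and GRCm38.p6, with no role or order. Whether reads were counted by strand is not given in the sources used here, so reads of a gene and an overlapping or antisense partner cannot be told apart, and reads shared with pseudogenes may be split. In every library FPKM multiplied by gene length was a whole multiple of a fixed step, with 100% of the nonzero values within 0.01 of a whole number. The reads behind each value could therefore be recovered and came to 16.1 to 28.7 M per library. The total by which the authors scaled each library differed from its recovered reads by -3.47% to 7.90%, so it was not the plain sum of reads. Recovered reads were not used in the main test.

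Genes with an FPKM of at least 1 in at least 4 of the 8 samples were tested, 11667 in all. FPKM was transformed to log2(FPKM + 1), which understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a trended empirical Bayes variance, no covariate and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05, two-sided. Single values were also compared by an exact two-sided permutation test, for which 4 against 4 samples allow no p below 0.0286. Altogether 38 gene lists were fixed before the data were examined, as were the test, the alternatives and the rule for naming genes. The 30 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes. Camera with an estimated correlation and limma's fry were run beside it. Fry tests a list against no change, not against the other genes. Ranges of a list's adjusted p over all alternatives include both tests. Counts of members past the threshold were made over all genes and after an adjustment over each list alone.

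The named genes are Tgfbr2, then up to 10 genes per direction with the largest change among those past the threshold whose 4 values all lie on the same side of all 4 control values, without predicted genes and pseudogenes. Where fewer passed, the next 5 by p in that direction were named as not past it. Up to 4 members with the smallest p were taken from each list described. Acta2, Col1a1, Col3a1, Postn, Fn1, Ccn2 (Ctgf in the file), Pdgfra, Pparg, Cebpa, Adipoq, Fabp4, Plin1, Lpl, Ptprc and Myh6 were named whatever their values; 1 further gene fixed for naming is not reported here. Coordinates are those of the deposited table (GRCm38), with exons from a matching annotation.

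The test was tried on simulated reads drawn for the real genes from the real means, depths and dispersions, with 200 genes changed in each of 5 runs of this comparison over a mean of 11491 genes. It recovered 43.5% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.1% of those changed 4-fold, and 5.13% of the calls were false. Genes were drawn as independent, without variation shared between them. The adjusted threshold is also stricter where fewer than 200 genes change. These shares may therefore not hold for the real comparison, where recovery may be lower. Camera with the preset correlation called a list of 25 genes raised 1.5-fold in 20 of 20 runs and a list of 25 unchanged genes in 1 of 20, with genes simulated as independent. A 1.5-fold shift is larger in size than every list mean in the real data (log2 fold changes of -0.23 to 0.39). These runs therefore do not show how often shifts of that size would be called. The list was first raised by a smaller fold, with the same 2 counts, and the fold was changed only because its number clashed with printed values in the text check.

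The alternatives were a pseudocount of 0.1, no filter and a stricter filter (FPKM of at least 5), median-of-ratios scaling, quantile normalization, conversion to TPM, protein-coding genes without mitochondrial genes, array weights, voom on recovered reads, the Xist minus Y-linked level and the macrophage marker level as covariates, leaving out each sample in turn, and 2 other thresholds. A correction for gene length and GC content, leaving out FTbR2KO 1 and TbR2fl/fl 5 together, and a block by neighbouring numbers in the sample titles were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.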

Results

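Transcriptomes of PDGFRα-sorted infarct fibroblasts were available from 4 samples labelled FTbR2KO and 4 TbR2fl/fl controls, all taken 7 days after coronary occlusion. Depth was 16.1 to 22.9 M reads in the FTbR2KO libraries (19.1 ± 2.95 M, SD, n = 4) and 21.2 to 28.7 M in the controls (26.5 ± 3.59 M, n = 4; exact permutation p = 0.0571). At least 1 read was found for 20736 to 23456 genes per library. Pearson's r of log2(FPKM + 1) across tested genes, which are not independent replicates, was 0.968 to 0.988 within groups and 0.962 to 0.985 between them. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 15.1. The main axis of variation, a principal component with 33.0% of the variance, set FTbR2KO 1 (score -24.4) and TbR2fl/fl 5 (-20.9) apart from the other libraries (-0.108 to 19.0), and so ran across genotype. On the second, with 22.7% of the variance, FTbR2KO 1 to 3 (6.77, 16.6 and 19.6) lay above all controls (-11.6 to -4.80) and FTbR2KO 4 (-9.05) among them (exact permutation p = 0.0857 between groups).

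The targeted gene was examined before any other. Tgfbr2, the receptor subunit that binds TGF-β ligands, lies on chromosome 9 from 116084293 to 116175360, minus strand. Its level was 58.2 ± 1.30 against 45.5 ± 3.86 FPKM (mean ± SD, n = 4 each) in the libraries labelled FTbR2KO and the controls. All 4 libraries labelled FTbR2KO lay above all 4 controls, the reverse of what their label says. The log2 fold change was 0.35 (SE 0.086, 95% confidence interval 0.16 to 0.55). The exact permutation p was 0.0286, the smallest this design allows, but limma's adjusted p was 0.571. The value covers the whole gene: the last exon of the longer transcript makes up 76.5% of the counted length and the largest internal exon, 800 bp from 116109504 to 116110303, makes up 9.77%. A gene-level FPKM therefore cannot show whether an internal exon was deleted, and directions below refer to the libraries as labelled. Levels given as 1 value against another are means ± SD of the 4 libraries labelled FTbR2KO against the 4 controls.

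**Figure D1:**
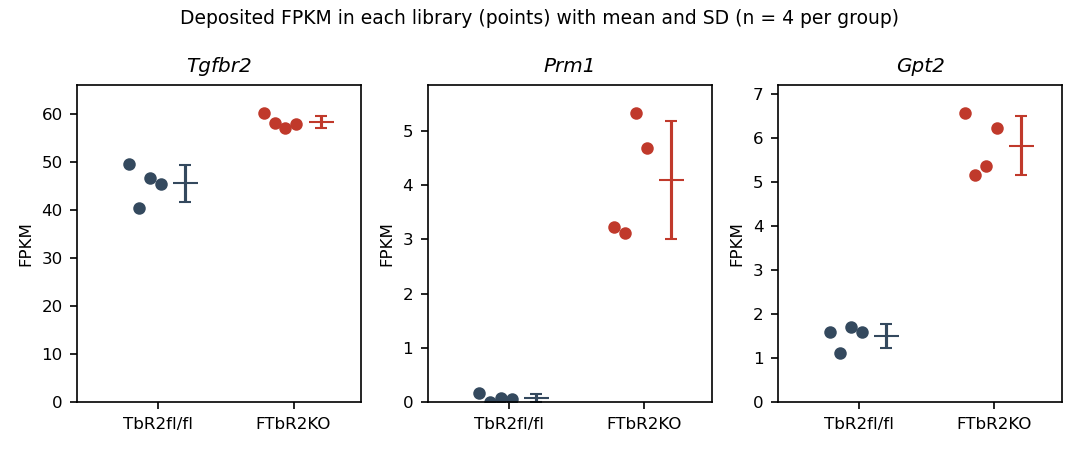
Deposited FPKM of Tgfbr2, Prm1 and Gpt2 in each of the 8 libraries (points; vertical axis, FPKM from 0), with the mean and SD of each group of 4 beside them. For all 3 genes the 4 libraries labelled FTbR2KO lie above the 4 controls.

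**Figure D2:**
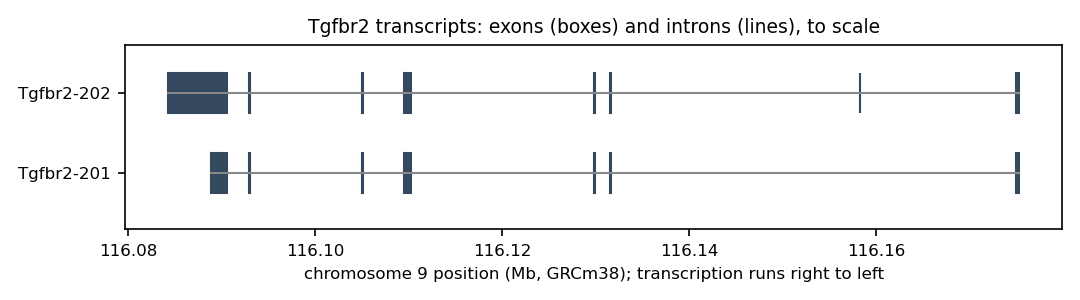
Exons (boxes) and introns (lines) of 2 Tgfbr2 transcripts, drawn to scale against the position on chromosome 9 in Mb. The last exon, at the left, holds 76.5% of the counted length of the gene.

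The genotype comparison asks how losing TbR2 alters the transcriptome of infarct fibroblasts. Of the 11667 genes tested, 2 rose and 0 fell in the libraries labelled FTbR2KO. Gpt2, which encodes the mitochondrial alanine aminotransferase, rose from 1.51 ± 0.262 to 5.83 ± 0.669 FPKM (n = 4 each), a ratio of means of 3.87. Prm1, which encodes protamine 1 and is normally a gene of maturing sperm, rose from 0.0815 ± 0.0743 to 4.09 ± 1.08 FPKM, which rests on 184 reads in the 4 libraries labelled FTbR2KO and 5 reads in the 4 controls.

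On the log2(FPKM + 1) scale Prm1 changed by 2.21 (SE 0.15) and Gpt2 by 1.45 (SE 0.10), each with a limma adjusted p of 0.000955 and with 4 of 4 libraries above every control. Prm1 (chromosome 16, 10796326 to 10805839, minus strand) overlaps an antisense gene and a pseudogene in the annotation, so its counting is uncertain. Gpt2 lies on chromosome 8 from 85492576 to 85527560, plus strand, and the 29 other tested genes within 1 Mb of it had log2 fold changes of -0.37 to 0.16. With a block for neighbouring title numbers neither gene passed (limma adjusted p = 0.125 for Prm1 and 0.0512 for Gpt2), although their log2 fold changes were 2.17 and 1.39. Over all alternatives the adjusted p ran from 0.000199 to 0.125 for Prm1 and from 0.000400 to 0.0512 for Gpt2. A stricter filter removed Prm1 from the test and left 1 gene past the threshold. Without FTbR2KO 4 the count was 8, with 6 genes higher and 2 lower. It was 3 with the Xist covariate, which added Cnmd (adjusted p = 0.0313), and 3 with the macrophage covariate or without TbR2fl/fl 8, each of which added 1 predicted gene (0.0359, lower, and 0.0187, higher).

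No other gene came near the threshold, the next smallest limma adjusted p being 0.571. At an unadjusted p under 0.05 there were 1004 genes, 436 higher and 568 lower, where 583 are expected if genes are independent, but 7 of the 35 splits of the libraries into 4 and 4 gave at least as many (highest other 2181). The 1004 also depended on the setting: limma put 645 genes at an unadjusted p under 0.05 after the length and GC correction. It put 491 there without FTbR2KO 2 and 2206 with array weights. The groups did not overlap for 515 genes (4.41%, against 2.86% by chance). None of the following passed the adjusted threshold in this comparison, and for each all 4 libraries labelled FTbR2KO lay on the same side of the controls. Cnmd, the cartilage matrix protein chondromodulin, measured 9.44 ± 4.61 against 1.82 ± 0.783 FPKM and S1pr3, a receptor for sphingosine-1-phosphate, 21.8 ± 3.73 against 13.4 ± 1.83 FPKM. Rbms3, an RNA-binding protein, had a log2 fold change of 0.35 (SE 0.078), Angpt4, an angiopoietin, 0.43 (SE 0.095) and Enpp6, a choline-specific phosphodiesterase, 0.44 (SE 0.10). On the low side, Ddt, a homologue of the cytokine MIF, measured 4.69 ± 0.717 against 8.24 ± 1.19 FPKM, and Azin2, an antizyme inhibitor, 5.62 ± 0.948 against 9.31 ± 0.938 FPKM. Snx8 had a log2 fold change of -0.43 (SE 0.081), the transcription factor gene Creb3l3 -0.49 (SE 0.092) and the ribosomal protein gene Rpl7a -0.87 (SE 0.15), whose reads can be shared with pseudogenes.

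**Figure D3:**
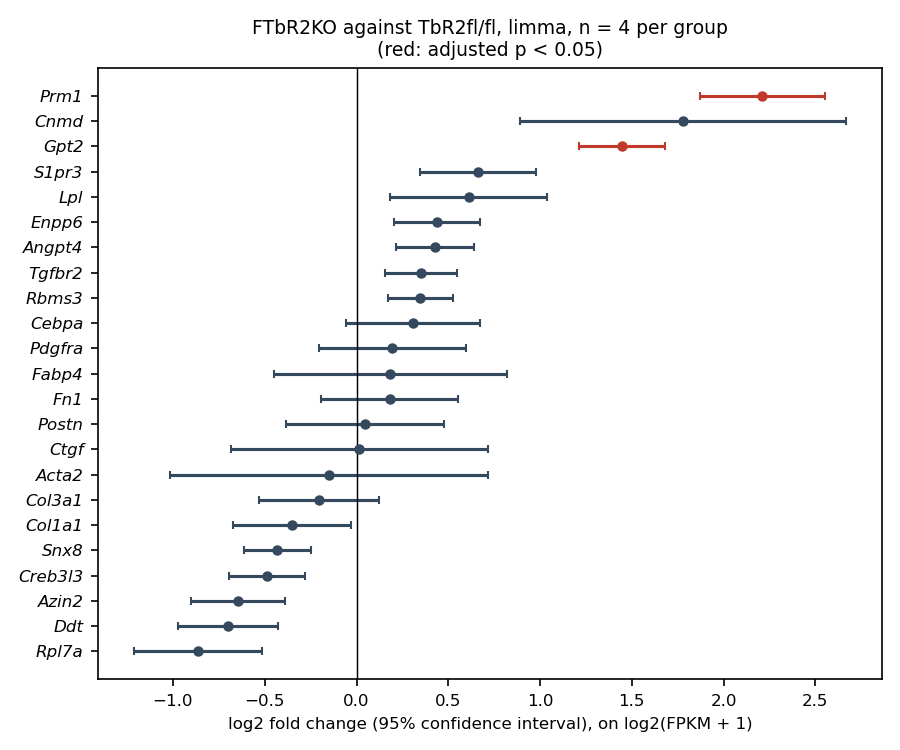
Log2 fold change of the named genes on the log2(FPKM + 1) scale (horizontal axis, points) with 95% confidence intervals (bars) from limma, libraries labelled FTbR2KO against controls, 4 each. Prm1 and Gpt2, in red, are the 2 genes past the adjusted threshold, and Tgfbr2 lies at 0.35. Col1a1 and Col3a1 lie below 0 here and above 0 after quantile normalization (0.039 and 0.045).

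Genes that TGF-β is known to induce did not move together. Of the 24 on the fixed list, all tested, 12 lay above 0 and 12 below, with a mean log2 fold change of 0.0025, a median of -0.0051 and a camera adjusted p of 0.932. Ctgf, the matricellular growth factor also called Ccn2, measured 879 ± 239 against 892 ± 351 FPKM. Smurf2, a ubiquitin ligase that acts on TGF-β receptors, had a log2 fold change of 0.16 (SE 0.074) and the tendon transcription factor gene Scx -0.35 (SE 0.23). The 24 contractile and myofibroblast genes split into 9 above 0 and 15 below (mean -0.058, camera adjusted p = 0.554), and their mean lay above 0 without FTbR2KO 1 (0.055) or TbR2fl/fl 8 (0.038). Acta2, which encodes the smooth muscle actin of myofibroblasts, measured 212 ± 76.6 against 239.7 ± 109 FPKM, so the difference was smaller than the spread between samples. Tagln (log2 fold change -0.38, SE 0.19) overlaps other annotated genes and its counting is uncertain. The value was -0.29 (SE 0.18) for Cnn1 and -0.33 (SE 0.25) for Tpm2. In none of these lists did a member pass the threshold over all genes or adjusted over the list alone.

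Several other lists were called by camera with the preset correlation: 9 of 30, 7 higher and 2 lower. The count was 5 with array weights and 2 without FTbR2KO 1 and TbR2fl/fl 5. None held with an estimated correlation, and none passed in fry, which tests against no change. Each of these 2 tests put 1 list at an unadjusted p under 0.05. In none of the 9 lists did a member pass over all genes or adjusted over the list alone. Fibrillar and fibril-associated collagens fell as a list: 12 of 13 members lay below 0, with a mean of -0.20 and a camera adjusted p of 0.00902 (adjusted p = 0.831 with an estimated correlation). The list's mean log2 level was 6.72 to 7.11 in the libraries labelled FTbR2KO and 7.14 to 7.24 in the controls. The exact permutation p was 0.0286, not adjusted for the number of lists. No other called list reached that p for its mean level. The same test gave 0.0857 for ribosomal protein genes and for the TGF-β superfamily, 0.143 for basement membrane genes and 0.171 for ERK and Akt feedback genes. For the remaining called lists it gave 0.343 (chemokines) to 0.486 (unfolded protein response genes). Col1a1, the main chain of type I collagen, measured 3934 ± 424 against 5005 ± 283 FPKM, with all 4 libraries labelled FTbR2KO below all controls (log2 fold change -0.35, SE 0.14), and Col1a2 1553 ± 186 against 1898 ± 70.7 FPKM. The log2 fold change was -0.20 (SE 0.15) for Col3a1 and -0.33 (SE 0.13) for Col16a1. After quantile normalization the list lost its call (camera adjusted p = 0.0887) and Col1a1 and Col3a1 lay above 0 (0.039 and 0.045). The list's call was also lost without FTbR2KO 1 (mean -0.12, adjusted p = 0.0679), a library in which its mean log2 level was 6.72 against 6.97 to 7.11 in the others of that label. It was lost without FTbR2KO 1 and TbR2fl/fl 5 together (adjusted p = 0.147), and over all alternatives its adjusted p ran from 0.000963 to 0.831.

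Basement membrane genes rose as a list, with 16 of 18 members above 0 (mean 0.14, camera adjusted p = 0.00902; adjusted p = 0.831 with an estimated correlation). Examples are Nid2 (35.6 ± 0.869 against 31.0 ± 1.52 FPKM) and Lama2 (73.3 ± 7.58 against 62.2 ± 7.64 FPKM), which encode nidogen 2 and a laminin chain. The call was lost without FTbR2KO 4 (mean 0.11, adjusted p = 0.0650), without TbR2fl/fl 6 (mean 0.083, adjusted p = 0.0865), without FTbR2KO 1 and TbR2fl/fl 5 together (mean 0.12, adjusted p = 0.0549) and with the title-number block (mean 0.083, adjusted p = 0.0586; 0.000509 to 0.831 over all alternatives). Ligands, receptors and Smads of the TGF-β superfamily rose as a list, with 19 of 27 above 0 (mean 0.11, camera adjusted p = 0.0117; adjusted p = 0.831 with an estimated correlation). Tgfb2, a TGF-β ligand, measured 15.5 ± 3.47 against 10.3 ± 1.08 FPKM, and Smad3, a signal transducer of the pathway, 17.2 ± 1.59 against 13.4 ± 2.08 FPKM. The log2 fold change was 0.23 (SE 0.086) for the BMP receptor gene Bmpr2. This call was lost without FTbR2KO 1 and TbR2fl/fl 5 together (mean 0.094, adjusted p = 0.0595; 0.00120 to 0.831 over all alternatives). Feedback genes of the ERK and Akt pathways rose as a list, with 17 of 24 above 0 (mean 0.12, camera adjusted p = 0.00902; adjusted p = 0.825 with an estimated correlation). Members included Spred1, an inhibitor of ERK signalling (18.5 ± 1.14 against 15.5 ± 1.35 FPKM), and the growth factor receptor gene Egfr (14.8 ± 0.623 against 12.7 ± 1.31 FPKM). Without TbR2fl/fl 5 the mean was smaller by over 1.5 times (mean 0.060, adjusted p = 0.0484; 0.000698 to 0.825 over all alternatives), and that library's mean log2 level was 3.24 against 3.45 to 3.51 in the other controls.

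Cytosolic ribosomal protein genes fell as a list, with 28 of 28 members below 0 (mean -0.23, camera adjusted p = 6.18e-08; adjusted p = 0.831 with an estimated correlation). Rpl23 measured 117 ± 12.6 against 154 ± 13.6 FPKM and Rpl30 31.1 ± 12.2 against 53.7 ± 11.3 FPKM. Chemokines and inflammatory cytokines rose as a list, with 17 of 22 above 0 (mean 0.24, camera adjusted p = 0.0159; adjusted p = 0.831 with an estimated correlation). The monocyte attractant gene Ccl7 measured 62.4 ± 20.3 against 34.5 ± 11.1 FPKM and the eosinophil attractant gene Ccl11 9.39 ± 2.93 against 5.58 ± 2.58 FPKM. The call was lost without FTbR2KO 3 (mean 0.10, adjusted p = 0.210), without TbR2fl/fl 5 (mean 0.13, adjusted p = 0.272), without FTbR2KO 1 and TbR2fl/fl 5 together (mean 0.16, adjusted p = 0.174), with no filter (mean 0.14, adjusted p = 0.336), with array weights (mean 0.14, adjusted p = 0.171) and after conversion to TPM (adjusted p = 0.123; 0.000176 to 0.871 over all alternatives). The mean was 0.38 without FTbR2KO 4 and 0.39 with the macrophage covariate. Unfolded protein response genes rose as a list, with 20 of 22 above 0 (mean 0.16, camera adjusted p = 0.0245; adjusted p = 0.831 with an estimated correlation), among them Sel1l (21.7 ± 2.14 against 18.6 ± 0.745 FPKM). Their control level was lowest in TbR2fl/fl 5, where the list's mean log2 level was 4.90 against 5.40 to 5.49 in the other controls. Without that library the mean was near 0 and the call was lost (mean 0.020, adjusted p = 0.581). It was also lost without FTbR2KO 2 (mean 0.050, adjusted p = 0.244), without FTbR2KO 3 (mean 0.078, adjusted p = 0.236), without FTbR2KO 1 and TbR2fl/fl 5 together (mean 0.13, adjusted p = 0.0634) and with array weights (mean 0.12, adjusted p = 0.0917; 0.000176 to 0.871 over all alternatives), while the mean was 0.27 without FTbR2KO 1 and 0.27 with the macrophage covariate. Epicardial and mesothelial markers, genes of the layer that covers the heart, rose as a list, with 10 of 10 above 0 (mean 0.39, camera adjusted p = 0.0441; adjusted p = 0.831 with an estimated correlation). Aldh1a2, which makes retinoic acid, measured 74.1 ± 15.7 against 49.5 ± 16.7 FPKM, and Upk3b 4.66 ± 4.18 against 2.41 ± 1.78 FPKM. This call was lost in 12 of 22 alternatives, with adjusted p from 0.00224 to 0.871. Without TbR2fl/fl 7 (mean 0.070, adjusted p = 0.653), FTbR2KO 1 (mean 0.17, adjusted p = 0.400) or FTbR2KO 3 (mean 0.25, adjusted p = 0.197) the mean fell by over 1.5 times, and without FTbR2KO 4 (0.68), without TbR2fl/fl 5 (0.60) and with a pseudocount of 0.1 (0.66) it was over 1.5 times as large. The other losses were with median-of-ratios scaling (adjusted p = 0.0518), quantile normalization (0.0733), TPM (0.508), array weights (0.0917), voom (0.0784), the Xist covariate (0.0551) and without FTbR2KO 1 and TbR2fl/fl 5 together (0.0625).

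**Figure D4:**
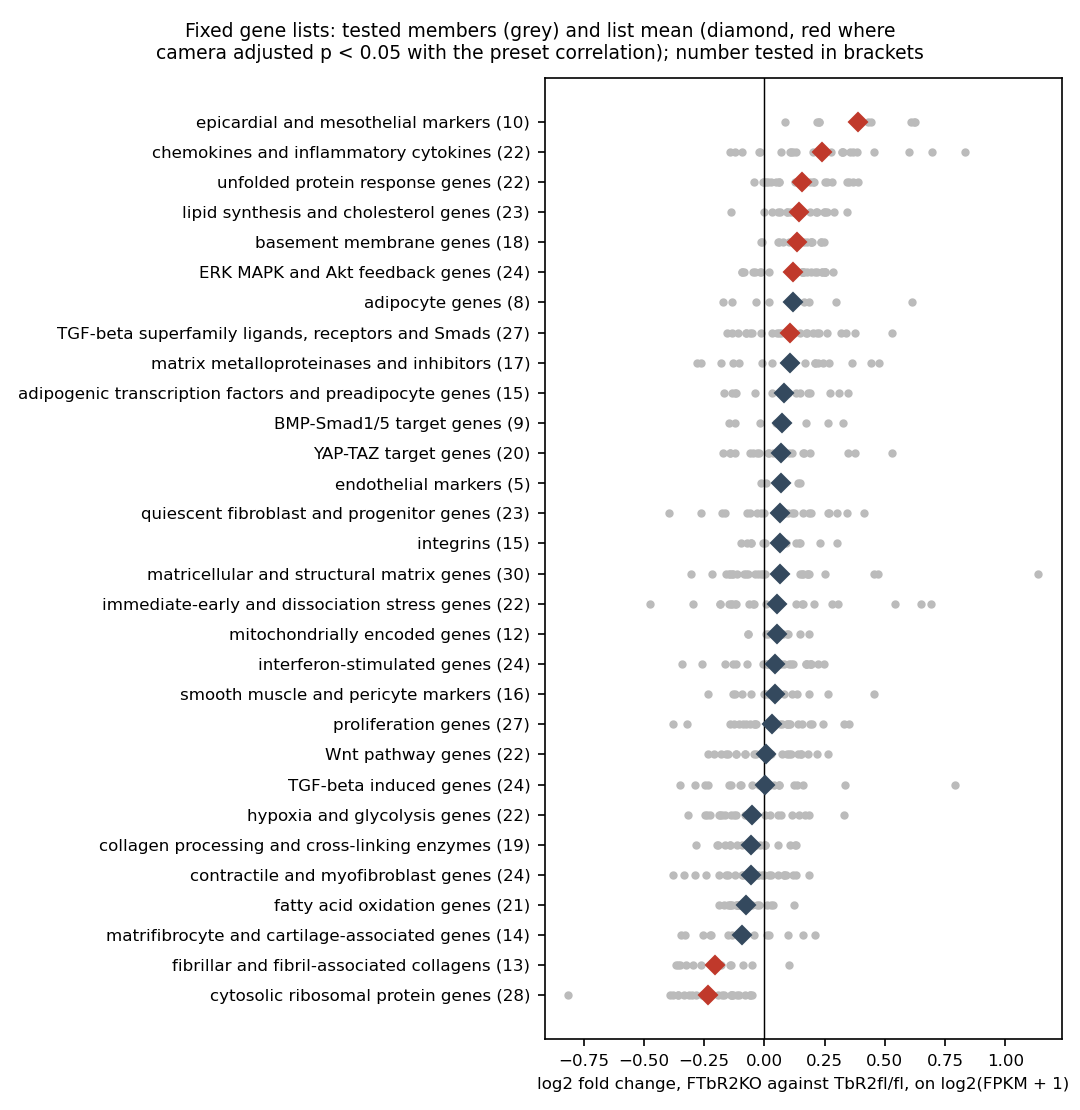
Log2 fold change (horizontal axis) of the tested members (grey points) of each of the 30 fixed lists, with the list mean as a diamond, red for the 9 lists called by camera with the preset correlation. List means run from -0.23 for ribosomal protein genes to 0.39 for epicardial markers. None of the 9 calls held with an estimated correlation, and the collagen list lost its call after quantile normalization, where Col1a1 and Col3a1 turned above 0.

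The series title speaks of adipocyte conversion, so adipocyte genes were examined as a separate question. Only cells sorted for PDGFRα were sequenced, so cells without that receptor would be missing. Scarce adipocyte transcripts here therefore do not argue against conversion. Mature adipocyte transcripts were scarce in both groups: of 30 genes on the list, 19 stayed under 1 FPKM in all libraries and 8 could be tested. Of these 8, 5 lay above 0 and 3 below (mean 0.12, camera adjusted p = 0.546), and without FTbR2KO 3 the mean was 0.061 (adjusted p = 0.815; 0.180 to 0.871 over all alternatives). Lpl, the lipoprotein lipase gene, measured 50.6 ± 11.3 against 32.6 ± 6.78 FPKM (log2 fold change 0.61, SE 0.19, limma adjusted p = 0.571), and Fabp4, a fatty acid binding protein gene, 1.91 ± 1.30 against 1.47 ± 0.674 FPKM. Pparg, the master regulator of adipogenesis, was below the filter at 0.635 ± 0.307 against 0.246 ± 0.102 FPKM (exact permutation p = 0.0857). Plin1, which coats lipid droplets, measured 0.174 ± 0.127 against 0.0145 ± 0.0132 FPKM, from 58 reads against 7 (exact permutation p = 0.0571), and Adipoq, the adiponectin gene, 0.0434 ± 0.0392 against 0.0438 ± 0.0421 FPKM. Adipogenic transcription factors and preadipocyte genes gave 10 of 15 above 0 (mean 0.080, camera adjusted p = 0.260), including Cebpa (13.0 ± 2.17 against 10.4 ± 2.65 FPKM) and Ebf2 (13.7 ± 1.32 against 11.3 ± 2.34 FPKM). That list passed after the length and GC correction (mean 0.12, adjusted p = 0.0418) and without TbR2fl/fl 7 (mean 0.13, adjusted p = 0.0413), and its mean was 0.027 without TbR2fl/fl 8 and 0.037 without FTbR2KO 1 (adjusted p from 0.0413 to 0.871 over all alternatives). Of 15 brown and beige adipocyte genes 4 could be tested, too few for a list test, and 11 stayed under 1 FPKM throughout. Genes of lipid and cholesterol synthesis rose as a list, with 21 of 23 above 0 (mean 0.14, camera adjusted p = 0.0159; adjusted p = 0.831 with an estimated correlation). Scd1, a fatty acid desaturase gene, measured 38.3 ± 3.43 against 32.6 ± 7.15 FPKM and Fasn, the fatty acid synthase gene, 15.6 ± 2.61 against 13.5 ± 1.70 FPKM. Without TbR2fl/fl 5, where the mean log2 level was 2.98 against 3.33 to 3.71 in the other controls, the mean was near 0 and the call was lost (mean 0.014, adjusted p = 0.541). It was also lost without FTbR2KO 2 (mean 0.040, adjusted p = 0.334), without FTbR2KO 1 and TbR2fl/fl 5 together (mean 0.075, adjusted p = 0.180) and with array weights (mean 0.10, adjusted p = 0.0917; 7.87e-06 to 0.871 over all alternatives), while the mean was 0.26 without TbR2fl/fl 8 and 0.24 with the macrophage covariate. Fatty acid oxidation genes had 17 of 21 below 0 (mean -0.077) and a camera adjusted p of 0.0502, just short of the threshold. They passed without FTbR2KO 1 (adjusted p = 0.0235), FTbR2KO 3 (0.0345), TbR2fl/fl 7 (0.0202) or TbR2fl/fl 8 (0.0157), with a pseudocount of 0.1 (0.0498), no filter (0.0362) or the macrophage covariate (0.0348), and were furthest from passing with the preset correlation without TbR2fl/fl 5 (0.504). In none of these lists did a gene pass over all genes or adjusted over the list alone.

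The remaining fibroblast lists were not called. Matricellular and structural matrix genes were evenly split, 15 above 0 and 15 below, with a mean of 0.063 and a median of -0.0030 (camera adjusted p = 0.540). Single libraries moved that mean by over 1.5 times: it was 0.00095 without TbR2fl/fl 5, 0.022 without FTbR2KO 2 and 0.13 without FTbR2KO 1. Within it Postn, the periostin gene, measured 1317 ± 282 against 1260.1 ± 175 FPKM, Fn1, the fibronectin gene, 1405 ± 285 against 1222 ± 82.4 FPKM, and Efemp1, the fibulin 3 gene, 28.7 ± 12.4 against 12.4 ± 6.29 FPKM. The camera adjusted p was 0.294 for collagen processing enzymes, 0.294 for matrifibrocyte genes, 0.0749 for matrix metalloproteinases and their inhibitors, 0.294 for integrins and 0.365 for quiescent fibroblast genes. Adamts4, an aggrecan-cleaving protease gene on the metalloproteinase list, measured 39.3 ± 6.21 against 28.0 ± 4.62 FPKM and Mmp23 82.2 ± 5.92 against 100 ± 8.70 FPKM. Among YAP-TAZ target genes (camera adjusted p = 0.163), Rbms3 passed adjusted over the list alone (limma adjusted p = 0.0295, log2 fold change 0.35, 4 of 4 libraries above every control), and 0 passed over all genes. In no other of the 38 lists did a member pass adjusted over the list alone. That adjustment was made in each list separately, with no correction across the 38 lists, so a single pass can arise by chance. Camera adjusted p was 0.496 for BMP target genes, 0.987 for Wnt pathway genes (mean 0.0048, median -0.0042), 0.294 for interferon-stimulated genes, 0.679 for proliferation genes and 0.679 for hypoxia and glycolysis genes. Some of these lists passed with 1 library left out: metalloproteinases without FTbR2KO 4 (camera adjusted p = 0.0207) or TbR2fl/fl 7 (0.0397), quiescent fibroblast genes without TbR2fl/fl 7 (0.00305), matrifibrocyte genes, lower, without TbR2fl/fl 6 (0.0367), integrins without FTbR2KO 1 (0.0461) or TbR2fl/fl 8 (0.0253), YAP-TAZ targets without FTbR2KO 1 (0.0371), interferon-stimulated genes without FTbR2KO 3 (0.00872) or TbR2fl/fl 5 (0.0487) and proliferation genes without FTbR2KO 1 (0.0461). Among proliferation genes Mki67 measured 3.32 ± 1.73 against 2.33 ± 1.09 FPKM. Pdgfra, the gene of the receptor used for sorting, measured 65.9 ± 13.5 against 57.6 ± 12.2 FPKM.

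Most markers of other cells were low in both groups. Ptprc, the leukocyte common antigen gene, was at 0.0149 ± 0.0132 against 0.00914 ± 0.0106 FPKM, and the cardiomyocyte myosin gene Myh6 at 0.252 ± 0.0773 against 0.269 ± 0.0853 FPKM. The most abundant macrophage marker, Lyz2, averaged 3.89 against 4.43 FPKM, and 16 of 23 macrophage markers stayed under 1 FPKM in every library. The same held for 18 of 23 cardiomyocyte markers, where Atp2a2, which fibroblasts can also express, led with 62.6 against 58.2 FPKM, and for 17 of 19 lymphocyte markers (Trac, 1.73 against 1.40 FPKM). It also held for 10 of 12 neutrophil markers (G0s2, 28.9 against 34.5 FPKM), 8 of 11 Schwann cell markers (Cdh19, 5.78 against 4.95 FPKM) and 4 of 8 erythroid markers (Hbb-bs, 4.35 against 7.30 FPKM). Endothelial markers (5 of 19 tested, camera adjusted p = 0.527) and smooth muscle and pericyte markers (16 tested, 0.5998) were not called. Immediate-early and dissociation stress genes were not called either, with a mean of 0.054 and a median of -0.044 (0.932), nor were mitochondrially encoded genes (0.483), whose share of reads was 0.835% in TbR2fl/fl 5 and 1.09% to 1.23% in the other 7 libraries. Xist, the transcript of the inactive X chromosome, was at 0.0561 FPKM in FTbR2KO 4 and 0.0215 in TbR2fl/fl 8 and at 30.7 to 49.7 in the other 6 libraries, so each group held 1 library with a male pattern.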

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

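The tests of Prm1 and Tgfbr2 and the count of splits for the ribosomal protein genes were chosen after those results were seen. The correction for gene length and GC content was also chosen after seeing the data. In this section, only its bounds, those for thinning and the split counts for genes and lists were written before those values were seen. A test of the region around Gpt2 was also run, after that result was seen, and argued against a regional change (median log2 fold change of -0.057 over the 29 neighbours within 1 Mb). Its row was then removed from the tables of predictions and tests, with the result known, to keep to 3 weighed patterns.

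In 360 groups of 4 libraries (each named gene, tested list and library measure, per genotype), 23 had a library whose gap to the rest was large against the whole range. Chance alone would give about 18, or 1 in 20. FTbR2KO 1 stood apart on the main axis of variation (score -24.4 against 3.62 to 5.89 in its group). It was low for P4ha3 (25.6 against 39.9 to 41.5 FPKM), Tpm2 (21.2 against 37.6 to 38.8 FPKM) and the mean log2 level of collagen processing enzymes (6.09 against 6.49 to 6.55), and high for Itga2 (1.90 against 1.59 to 1.64 FPKM). TbR2fl/fl 5 was low for the mean log2 level of unfolded protein response genes (4.90 against 5.40 to 5.49), matricellular genes (7.74 against 7.96 to 8.00) and mitochondrially encoded genes (6.62 against 7.25 to 7.35). It was also low for Dnajc3 (29.3 against 37.3 to 38.4 FPKM) and the share of mitochondrial reads (0.835% against 1.17% to 1.20%). TbR2fl/fl 7 had 21.2 M reads against 27.7 to 28.7 M in the other controls, and 21.7 FPKM of Efemp1 against 8.54 to 10.4. FTbR2KO 2 was apart for Ptprc (0.0346 against 0.00717 to 0.00944 FPKM), Nid2 (34.3 against 35.9 to 36.1 FPKM), Angptl7 (14.2 against 20.9 to 21.9 FPKM) and Cdkn2a (2.46 against 1.49 to 1.64 FPKM). FTbR2KO 3 was apart for Fabp4 (3.87 against 1.21 to 1.36 FPKM), Isg15 (20.95 against 27.7 to 28.6 FPKM) and Kcnj8 (3.91 against 2.40 to 2.63 FPKM). FTbR2KO 4 was high for Scx (11.9 against 7.06 to 7.61 FPKM) and Loxl1 (742 against 607 to 609 FPKM). TbR2fl/fl 6 was low for Ly6c1 (18.7 against 22.7 to 22.9 FPKM) and Asap1 (7.58 against 8.20 to 8.30 FPKM).

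The 8 libraries can be split into 4 and 4 in 35 ways. The real split gave 2 genes past the threshold, and 3 of the 35 splits, the real one included, gave at least as many, so chance cannot be excluded from the count alone. The highest count among the others was 30, from FTbR2KO 1, FTbR2KO 3, TbR2fl/fl 5 and TbR2fl/fl 7 against the rest, which points to a structure of the samples, though this split was picked as the highest and no test here says what the structure is. For the 9 lists called by camera with the preset correlation, 17 of the 35 splits gave at least as many and the highest other count was 17, so chance cannot be excluded. The median count of lists among the other splits was 8.

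Prm1, a sperm gene, had 31 to 61 reads in each library labelled FTbR2KO and 0 to 3 in each control. The tables argue against RNA from testis or germ cells, since 6 other spermatid genes (Prm2, Tnp1, Tnp2, Odf1, Smcp and Akap4) had 5 reads together in the 4 libraries labelled FTbR2KO, where Prm1 had 184. They also argue against a rise shared by the surrounding region. The 15 other tested genes within 500 kb had a median log2 fold change of 0.018, with values from -0.72 to 0.18. A protamine 1 terminator, a sequence used in some transgene cassettes, may have been carried by the recombinase transgene of the knockout mice; all 8 libraries met the bounds set for this, but the bounds were set after the reads had been seen and lend it no support. That cannot be told apart from an effect of the genotype, because the transgene would be in the same 4 libraries and the FPKM table holds no read positions.

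Tgfbr2 was higher in the libraries labelled FTbR2KO. Loss of 1 internal exon predicts a gene-level value that is lower, by at most the 9.77% that the largest internal exon contributes. The other internal exons each hold 0.916% to 2.33% of the counted length, so the predicted fall may be very small. The lower 95% limit of the log2 fold change was 0.16, so exon loss alone does not give the measured value. Whether the groups carry each other's labels cannot be told apart from correct labels. The only list set against this, the genes that TGF-β induces, moved neither way (a limma camera p of 0.899). Fibrillar collagens, not chosen for this test, were lower as labelled (mean log2 fold change -0.20). Their camera call did not hold with an estimated correlation (adjusted p = 0.831), so they do not decide it either. Prm1 reads would go with the labels as given if they came from the recombinase transgene, which is itself open. A response of the remaining transcript to receptor loss was not tested and stays open.

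Ribosomal protein genes were lower in the libraries labelled FTbR2KO, whose depth was lower on average but overlapped that of the controls. Thinning every library to 16.1 M reads left the list's mean log2 fold change at -0.23, but hardly moves genes this abundant whatever the cause, and single libraries do not all follow depth (mean log2 level 7.60 in FTbR2KO 4 with 22.9 M reads, 7.77 in TbR2fl/fl 7 with 21.2 M and 7.55 in TbR2fl/fl 5 with 27.7 M) but are too few to exclude it. Across genes, log2 fold change varied with gene length (Pearson's r = 0.287) and GC content (Spearman's rho = -0.409), and genes are not independent replicates. A correction for both took -0.056 (SE 0.037 between libraries, 95% confidence interval -0.15 to 0.036) off the list mean and left -0.18, which argues against these trends as the whole cause, not as a part of it. What stays open is depth, chance, since 3 of the 35 splits gave a list mean as far from 0 (highest other 0.31), camera called the list in 19 of the 35 and its adjusted p was 0.831 with an estimated correlation, and an effect of genotype.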

How the results depend on the processing

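The length and GC correction, the removal of FTbR2KO 1 with TbR2fl/fl 5, and the block by title numbers were chosen after seeing the data. Prm1 and Gpt2 were both past the threshold in 22 of the 24 alternatives for the gene count. For 2 of these, the other thresholds on the main fit, the main values of both genes fixed the outcome. The count was 1 with an FPKM of at least 5, where Prm1 was no longer tested. It was 0 with the title-number block, where limma put 957 genes at an unadjusted p under 0.05. The cause of the loss was not tested. The block leaves TbR2fl/fl 6 on its own and takes up degrees of freedom, so the loss alone does not show a batch effect. That block joins samples whose title codes lie close together. It puts FTbR2KO 1 with TbR2fl/fl 5, which stand apart together on the main axis, and FTbR2KO 4 with TbR2fl/fl 8, the 2 libraries with a male pattern. Its remaining mixed group is FTbR2KO 2 and 3 with TbR2fl/fl 7. Their scores on the second axis were 16.6 and 19.6 against -11.6. That axis parts FTbR2KO 1 to 3 from all controls, so it cannot test the block. FTbR2KO 3 correlated less with TbR2fl/fl 7 (Pearson's r = 0.973) than with TbR2fl/fl 6 (0.980) or 8 (0.979). For FTbR2KO 2 the values were 0.977 with TbR2fl/fl 7, 0.978 with TbR2fl/fl 6 and 0.976 with TbR2fl/fl 8. FTbR2KO 4 correlated slightly less with TbR2fl/fl 8 (0.9847) than with TbR2fl/fl 6 or 7 (0.9854 each), and least with TbR2fl/fl 5 (0.976). FTbR2KO 1 correlated more with TbR2fl/fl 5 (0.982) than with the other controls (0.962 to 0.975). The data thus do not decide whether the block holds. What the codes mean is not given in the sources used here. Leaving out a sample at a time gave 2 to 8 genes, and the 8 came without FTbR2KO 4. Tgfbr2 kept its direction and stayed short of the adjusted threshold in every alternative, with log2 fold changes of 0.30 to 0.52.

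The count of 9 lists became 5 with array weights, 2 without FTbR2KO 1 and TbR2fl/fl 5, 0 with an estimated correlation and 0 in fry, and 7 to 12 when samples were left out in turn. Of these, the estimated correlation allows for genes that vary together. That may not be the whole reason for its lower count. Camera's unadjusted p also rose for adipocyte genes (0.418 to 0.435), whose estimated correlation was below 0 (-0.059). The cause of the other changes in the count was not tested. Among lists not called, the title-number block called matrifibrocyte genes (camera adjusted p = 0.0334), proliferation genes (0.0398) and immediate-early genes (0.0349), the macrophage covariate called matrifibrocyte (0.0246) and proliferation genes (0.0171), and the length and GC correction called metalloproteinases (0.0296). Conversion to TPM moved the median log2 fold change of all genes to 0.15, so lists were read against that shift and the means of all 9 called lists moved by over 1.5 times; Gm23935, a short RNA gene, took 8.12% to 24.7% of the FPKM sum.

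Direction was followed for the called lists and the TGF-β induced, contractile, adipocyte, adipogenic and matricellular lists only. Genes other than Prm1, Gpt2 and Tgfbr2 were followed with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization and samples left out in turn. Outside that set, immediate-early genes were higher by camera and lower by fry. Within it, direction turned for the following, none of them past a threshold, and the cause was not tested. Camera's direction for the TGF-β induced genes turned with TPM (mean 0.16), array weights (-0.029) and without FTbR2KO 1 and TbR2fl/fl 5 (-0.024). For the contractile genes it turned with an FPKM of at least 5 (-0.036), the macrophage covariate (0.058) and without those 2 samples (-0.031). With samples left out in turn, the means ran from -0.056 to 0.036 and from -0.14 to 0.055. Quantile normalization, which forces the highest values of all libraries to be equal, turned Col1a1 (0.039) and Col3a1 (0.045). Leaving out a sample at a time turned Acta2 (-0.37 to 0.16), Postn (-0.052 to 0.20), Ctgf (-0.21 to 0.24), Fabp4 (-0.092 to 0.35), Tek (-0.049 to 0.21), Ecscr (-0.21 to 0.19), mt-Cytb (-0.0033 to 0.21), mt-Nd4 (-0.059 to 0.16) and mt-Nd4l (-0.036 to 0.20). Of the other single-gene values, 1515 kept direction and side of the threshold. Depth limits low genes most: Prm1 in the controls rests on 5 reads.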

Other observations

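Genes of the circadian clock, which are on none of the 38 fixed lists, were looked at after Dbp, a clock output gene outside the naming rule, had been seen at 1.93 FPKM in the libraries labelled FTbR2KO and 4.74 in the controls (log2 fold change -1.06, SE 0.27, 4 of 4 libraries below every control, not past the adjusted threshold). Of 8 other output genes tested, 7 lay below 0 and Hlf at 0.031 (SE 0.22). The log2 fold change was -0.86 (SE 0.42) for Nr1d1, which encodes the repressor REV-ERBα and averaged 12.6 against 19.8 FPKM, -0.61 (SE 0.24) for Nr1d2, -0.44 (SE 0.14) for Tef and -0.33 (SE 0.13) for Per3. Of the genes that peak at the opposite phase, 5 of 5 lay above 0. The log2 fold change was 0.25 (SE 0.099) for Arntl, the gene of the activator BMAL1, 0.45 (SE 0.14) for Npas2, which averaged 9.33 against 6.65 FPKM, 0.32 (SE 0.094) for Clock and 0.45 (SE 0.25) for Cry1. None of these genes passed limma's adjusted threshold.

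The hypothesis of a shift in the time of day at which tissue was collected was written down after Dbp and before the other clock genes were tested. The count of splits for them was chosen after that test. Camera with the preset correlation put the 8 tested clock output genes other than Dbp lower (mean -0.35, p = 0.000572) and the 5 opposite-phase genes higher (mean 0.35, p = 4.56e-05). Clock genes vary together and are not independent of Dbp, so these p-values are too small; with an estimated correlation camera gave p = 0.0658 and 0.0218. The mean log2 level of output minus opposite-phase genes was -0.85 ± 0.41 in the libraries labelled FTbR2KO and -0.16 ± 0.081 in the controls (n = 4 each, exact permutation p = 0.0286, the smallest possible), and 1 of the 35 splits, the real one, gave a difference that large (-0.70, against 0.60 for the highest other). That is the least share this design can give, and Dbp, which led to these genes, was picked for its difference, so chance is not excluded for the pattern. A different time of collection may separate the groups, and an effect of genotype on the clock stays open, because the labels used here give no time of day.

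Leaving out FTbR2KO 4 added 6 genes past the threshold, all chosen after their values were seen. In most of them FTbR2KO 4 resembled the controls. The pseudogene BC002163 was at 20.8 to 36.2 FPKM in the other 3 libraries labelled FTbR2KO, at 0.274 in FTbR2KO 4 and at 0.111 to 1.07 in the controls. Sned1 was at 29.3 to 43.8 FPKM in the same 3 libraries, at 3.93 in FTbR2KO 4 and at 3.45 to 9.13 in the controls. Tomm7 was at 6.97 to 7.78 FPKM in those 3, 16.3 in FTbR2KO 4 and 13.3 to 18.6 in the controls, and Vkorc1 at 9.39 to 10.9, 18.8 and 17.7 to 19.1 FPKM. Igfbp5 followed the same order (69.1 to 91.3, 30.6 and 27.7 to 39.8 FPKM). The remaining gene was Cnmd. For Prm1 (4.68 FPKM, 61 reads) and Gpt2 (6.23 FPKM) FTbR2KO 4 lay with the other libraries of its label.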
